A study of Mus musculus with 5 samples.

How the data were processed

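Lineage-negative thymocytes representative of the DN3 and DN4 stages were measured with the droplet 3′ kit of version 2, loaded for 6000 cells per sample, in 3 Rptor knockout and 2 wild-type samples. The deposited matrices hold raw UMI counts per gene and cell barcode, 27998 genes by 25160 barcodes over the 5 samples. The submitters' processing notes name Cell Ranger 1.3 and genome build mm10, and give no further settings. The barcodes were already limited to called cells, with 5599, 4498 and 5991 in knockout and 4468 and 4604 in wild type. The deposited UMIs per sample came to 35584256, 29579151, 38439962, 30798567 and 40113304 in that order. Gene coordinates came from the GENCODE M21 annotation, which gave a position for 27722 of the gene identifiers.

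Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, and Scrublet, as in scanpy 1.11.5, was run per sample. By a rule set before the data were examined its automatic threshold was used only where it marked at least 0.5% of a sample. It removed 156, 102 and 165 knockout cells and no wild-type cells, where it marked 0.0671% and 0.0434%. This left 24724 cells with median mitochondrial shares of 0.761%, 0.814% and 0.792% in knockout and 1.03% and 0.919% in wild type. Cells were clustered by the Leiden method (igraph 0.11.9, resolution 1) on 2000 variable genes chosen with the sample as batch, 30 principal components and 15 neighbours. T cell receptor segment genes, sex-linked genes and Rptor were left out, and no batch correction was made. A cluster took a class name where at least 3 markers of a fixed list, and at least 0.5 of the measured ones, were at least 1.5-fold higher than in the other cells. The mean log2 ratio also had to be at least 0.5 with a pseudocount of 5 CPM, and its top 10 genes had to hold no more markers of another list. The marker lists were fixed before the data were examined and these naming criteria were written afterwards.

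UMI counts were summed over all kept cells of a sample, and over each named class with at least 30 cells in every sample. Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM factors, filterByExpr by group, Benjamini-Hochberg adjusted p under 0.05). CPM values use TMM-scaled library sizes and are given as mean and SD of the samples. The SE of a log2 fold change was taken as its absolute value over the square root of the quasi-likelihood F statistic. It therefore does not carry the degrees of freedom of the test. All adjusted p-values of single genes come from edgeR unless DESeq2 1.42.0 is named, and those of lists from camera or fry in limma 3.58.1 on voom values. The interaction of genotype and class was tested in edgeR with the sample as a block, between the classes with the most wild-type cells. 27 pathway lists, a handling stress list, a sex-linked list and the marker lists were written before the data were examined. camera used its preset correlation of 0.01, an estimated correlation and fry served as alternatives, and lists with at least 5 tested genes entered the correction. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs (100, 53, 137, 50 and 0 cells had fewer and were left out). These and the class shares were compared by an exact two-sided permutation test over the 10 ways to choose 2 of 5 samples, whose smallest p is 0.1.

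Named genes followed a rule set before the data were examined. It took a fixed set of genes, the 8 largest rises and 8 largest falls over all cells (4 and 4 in each class and in the interaction) and up to 4 genes with the smallest p of each list. The rises and falls had adjusted p under 0.05, a mean of at least 10 CPM and all knockout samples on the same side of both wild-type samples. Blcap and Igf2 were chosen after their values were seen. Nnat, H19 and Cdkn1c came in by the rule, and their values had been seen before imprinted genes were counted. T cell receptor segment and constant genes were not analysed here, and Xist and other sex-linked genes were used only as a check of the list. Intervals and floors cover counting error only, and a floor is 3 counts over a group.

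On data simulated from the fitted spread, with 200 genes changed, the test recovered 65.7%, 84.8% and 96.9% of genes changed 1.5-fold, 2-fold and 4-fold over all cells. The shares were 60.6%, 85.1% and 98.5% in the DN3-like, 56.9%, 83.6% and 96.9% in the S-phase-like and 68.2%, 93.6% and 96.9% in the G2-or-M-like class. They were 50.7%, 71.6% and 97.0% for the interaction. camera called a list lowered by 0.4 on the log2 scale in 20 of 20 simulations and 0 of 480 unchanged lists. The simulated genes varied independently of each other, so these counts do not test the preset correlation against genes that vary together. The replicates of a group differed by more than counting error, with a chi-square per degree of freedom between 8.74 and 36.1 for pairs of samples.

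Alternatives tried were DESeq2, library sizes without TMM factors, no filter on low counts, each replicate left out and the replicate number as a block. Number 3 occurs only in knockout, so the block fits that sample exactly. Other cell filters were 1000 genes and 5% mitochondrial UMIs, all barcodes, no doublet removal and T-lineage cells alone. Sums were also made from cells thinned to 2000 UMIs, without ribosomal protein and mitochondrial genes, and with the same weight for each class (limma-trend, pseudocount 1 CPM). That weighting took named classes and unnamed clusters with at least 30 cells in every sample, and so left out 29.4%, 29.4% and 34.8% of knockout and 17.5% and 18.9% of wild-type cells. For class and UMI shares the alternatives were resolution 0.5, cell-cycle genes left out of the clustering, a clustering of wild-type cells alone with knockout cells projected, and thinning to 1000 UMIs or none. Added after the data were seen were removal of the same share of high-scoring doublets from every sample, droplets with over 5% haemoglobin UMIs left out, and classes of the wild-type clustering in the class tests. Also added were class sums thinned to 3377434 UMIs, lists tested in class sums, the cycling classes as 1 class and genes called in the all-cell test left out of the clustering. Further software was Python 3.11.15, anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.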

Results

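Thymocytes from 6- to 10-week-old mice were sorted as negative for lineage markers, CD4, CD8, both kinds of T cell receptor and CD44. This gate holds the DN3 and DN4 stages around β-selection, and the cells were profiled by droplet single-cell RNA sequencing of 3′ ends. 3 samples carried a knockout of Rptor, which encodes RAPTOR, the scaffold protein of the growth-controlling kinase complex mTORC1, and 2 samples were wild type. The deposited counts of unique molecular identifiers (UMIs, 1 per captured transcript) summed to 35584256, 29579151 and 38439962 in the knockout samples. They summed to 30798567 and 40113304 in the wild-type samples. After filtering, 5441, 4395 and 5824 knockout cells and 4464 and 4600 wild-type cells remained. The median UMIs per cell were 5439, 5574 and 5667 in knockout and 4523.5 and 6157.5 in wild type. The labels do not say that the replicates are separate animals, so the p-values measure the spread between samples.

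The comparison of all kept cells asked what the loss of RAPTOR changes in these precursors, in a series whose title concerns metabolic signalling and the choice between the αβ and γδ T cell lineages. Nnat is an imprinted gene for the small membrane protein neuronatin (chromosome 2, 157560078 to 157562522, GRCm38). It rose from 0.149 ± 0.039 CPM (UMIs scaled to library size; SD, n = 2) in wild type to 184.9 ± 8.13 CPM (SD, n = 3) in knockout. Its UMI counts were 6064, 5152 and 6809 in the knockout samples and 4 and 7 in the wild-type samples. Cd2, an adhesion receptor of T cells, rose 5.21-fold, from 16.5 ± 4.78 to 86.2 ± 9.21 CPM. Rorc, which encodes the RORγt factor of double-positive thymocytes, rose 3.38-fold, from 10.7 ± 0.472 to 36.1 ± 1.05 CPM. Dtx1, a Notch target, rose 3.24-fold, from 34.5 ± 3.98 to 112 ± 8.23 CPM. Ccr9, a chemokine receptor of thymic homing, fell from 61.1 ± 6.06 to 23.2 ± 3.06 CPM.

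The other large rises, as log2 fold change ± SE, were those of Arsi (2.61 ± 0.11) and Mllt4, which encodes the junction protein afadin (2.10 ± 0.13). The imprinted long non-coding RNA H19 rose by 1.94 ± 0.26, and Socs2, a cytokine signalling inhibitor, by 1.88 ± 0.22. The other large falls were those of the chaperone genes Hsph1 (-1.45 ± 0.11) and Hsp90aa1 (-1.14 ± 0.09), the actin-severing Scin (-1.39 ± 0.30) and Dqx1 (-1.37 ± 0.16). Cdk5rap1 (-1.24 ± 0.19), Ttll9 (-1.23 ± 0.12) and the methionyl-tRNA synthetase gene Mars (-1.21 ± 0.14) fell as well. Socs2 did not pass the test without wild-type replicate 1 (edgeR adjusted p = 0.0661) or 2 (0.051). Scin did not pass it without knockout replicate 3 (edgeR adjusted p = 0.121) or wild-type replicate 1 (0.0502). H19 and Dqx1 did not pass when each class of cells had the same weight in every sample (limma adjusted p = 0.0742 and 0.252), nor did H19 with the replicate number as a block (edgeR adjusted p = 0.274). Hsph1 and Hsp90aa1 also stand on the list of handling stress genes, of which 5 rose and 6 fell among the 20 tested (6 and 6 adjusted over the list alone). edgeR's quasi-likelihood test called 3444 of 12455 tested genes, 1608 higher and 1836 lower in knockout. With library sizes in place of TMM factors the split was 965 higher and 1935 lower, 33.3% higher against 46.7%. The number of calls was 1956 without wild-type replicate 1 and 1397 when every cell was thinned to 2000 UMIs. It was 1094 when each class had the same weight, 264 higher and 830 lower (24.1% higher), and 196 of the 3444 genes had the other sign there. That weighting left out classes and clusters with fewer than 30 cells in a sample, 29.4%, 29.4% and 34.8% of knockout and 17.5% and 18.9% of wild-type cells. The left-out cells included the double-positive-like class.

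**Figure D1:**
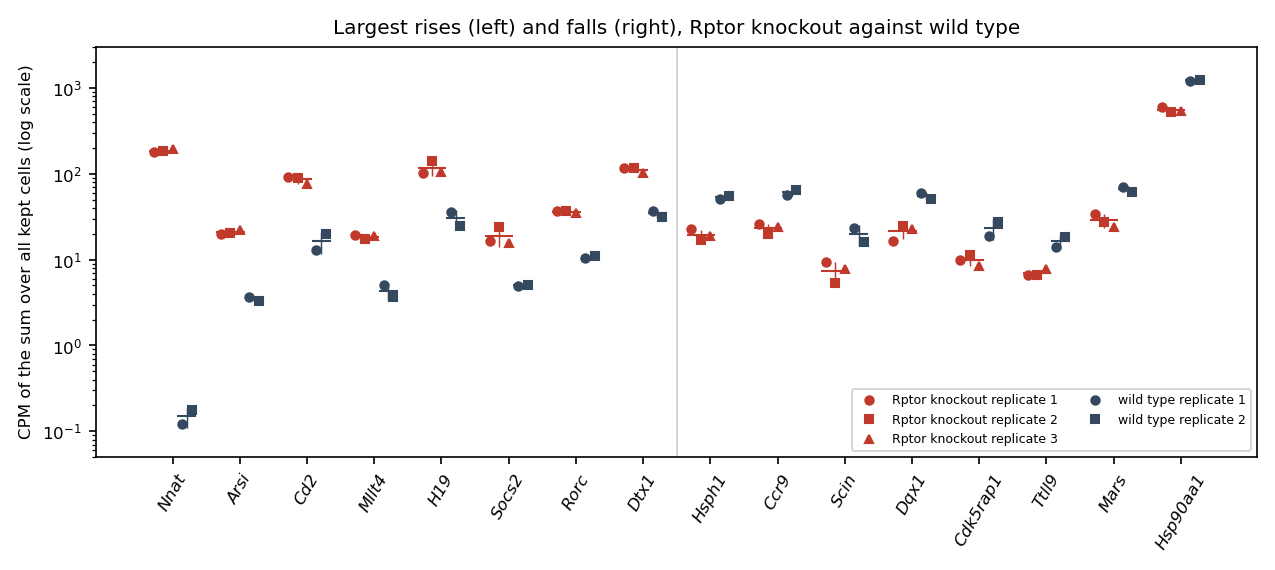
Level in CPM (log scale) of the genes with the largest rises (left) and falls (right) in the sum over all kept cells, with a point for each of 3 knockout and 2 wild-type samples and lines for the mean and SD of each group. Nnat is at 0.149 CPM on average in wild type and 184.9 in knockout, a wider gap than for any other gene drawn.

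Rptor itself (chromosome 11, 119602905 to 119899576) was at 18.2 ± 0.535 CPM (SD, n = 3) in knockout and 19.4 ± 0.521 CPM (SD, n = 2) in wild type, with an edgeR adjusted p of 0.388. The labels do not give the deleted part of the gene, and 3′ tags from outside that part check nothing about the deletion. Mtor, the kinase of the complex, had a log2 fold change of -0.12 ± 0.10 (SE; edgeR adjusted p = 0.367) and Rictor, the scaffold of mTORC2, one of 0.18 ± 0.08 (edgeR adjusted p = 0.126).

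Several genes that mark the path from DN3 to the double-positive stage moved. The sums count each cell by its UMIs, so such a marker can also move with the share of UMIs held by 1 class of cells. Il2ra, the CD25 chain that defines DN3 cells, rose from 224 ± 11.2 to 367 ± 22.0 CPM, and Ptcra, the pre-T cell receptor α chain, rose from 223 ± 10.1 to 315 ± 13.3 CPM. Cd8b1 rose from 83.9 ± 19.5 to 178 ± 24.7 CPM, Cd4 from 1.05 ± 0.414 to 2.45 ± 0.574 CPM, and the costimulatory receptor Cd27 from 267 ± 4.25 to 372 ± 10.1 CPM. On the log2 scale Cd8a rose by 0.53 ± 0.12 and the γδ lineage factor Sox13 by 0.72 ± 0.14. Tfrc, the transferrin receptor, fell by 0.76 ± 0.10 and Cd24a by 0.36 ± 0.08. Cd8a did not pass without wild-type replicate 1 (edgeR adjusted p = 0.092), Cd8b1 without knockout replicate 3 (0.0567) and Cd4 without wild-type replicate 2 (0.0596). With the same weight for each class, and without the double-positive-like class, the value of Cd8a was -0.48, and Ptcra, Cd4, Sox13, Cd27 and Cd24a did not pass (limma adjusted p = 0.0917, 0.0697, 0.116, 0.92 and 0.368). In thinned cells Cd27 did not pass either (edgeR adjusted p = 0.0971). Id3, a target of strong receptor signals, was at 67.8 ± 15.8 CPM in knockout and 118 ± 11.1 CPM in wild type but did not pass (edgeR adjusted p = 0.0858). It passed without knockout replicate 2 (edgeR adjusted p = 0.000488) or 3 (0.0427), with library sizes alone (0.00993), without a filter on low counts (0.0345), with the replicate number as a block (0.000229) and in thinned cells (0.029). It also passed with DESeq2 (adjusted p = 0.0105) and with the same weight for each class (limma adjusted p = 1.5e-05). Rag1 had a log2 fold change of -0.07 ± 0.08 and Myc one of -0.17 ± 0.10, and neither passed. The Rag1 value was 0.00 without knockout replicate 2, and that of Myc was 0.01 without wild-type replicate 1 and -0.35 without wild-type replicate 2, where it passed. Myc also passed with the replicate number as a block (-0.18, edgeR adjusted p = 0.0391). Mki67 (0.20 ± 0.09) did not pass, but it did without knockout replicate 2 (edgeR adjusted p = 0.0262), in thinned cells (0.00142), without a filter on low counts (0.0418) and with the same weight for each class (limma adjusted p = 0.00384). T cell receptor genes were not analysed here.

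The gene lists, fixed before the data were examined, showed lower levels of growth and biosynthesis genes. Of 40 ribosome biogenesis genes, 38 fell and 0 rose (38 and 0 adjusted over the list alone). Heatr1 (-0.79 ± 0.09), Bop1 (-0.89 ± 0.10) and Nolc1 (-0.65 ± 0.08), whose products assemble ribosomal subunits, were among them. Ribosome biogenesis had a camera adjusted p = 1.6e-18 (adjusted p = 0.28 with an estimated correlation). Of 30 genes of sterol and fatty acid synthesis, 26 fell (26 adjusted over the list alone). They included Fdps (-1.02 ± 0.08) and Hmgcs1 (-0.98 ± 0.09) of the mevalonate pathway and the sterol demethylase Cyp51 (-0.83 ± 0.09). Sterol and fatty acid synthesis had a camera adjusted p = 5.2e-14 (adjusted p = 0.253 with an estimated correlation). MYC targets had 20 falls among 25 genes (21 adjusted over the list alone), with the mitochondrial chaperone Hspd1 at -0.96 ± 0.09 (camera adjusted p = 2.0e-12; adjusted p = 0.253 with an estimated correlation). ATF4 targets and amino acid synthesis had 19 falls and 1 rise among 26 genes (19 and 2 adjusted over the list alone). Shmt2 (-0.78 ± 0.08), Mthfd2 (-0.67 ± 0.09) and Phgdh (-0.64 ± 0.09), enzymes of serine and folate metabolism, fell in it. ATF4 targets had a camera adjusted p = 1.7e-07 (adjusted p = 0.253 with an estimated correlation).

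In energy metabolism, nuclear-encoded oxidative phosphorylation had 43 falls and 2 rises among 85 genes (47 and 3 adjusted over the list alone). Cytochrome c, Cycs, fell by 0.90 ± 0.08 on the log2 scale while Cox7a2l, a supercomplex assembly factor, rose by 0.73 ± 0.09. Oxidative phosphorylation had a camera adjusted p = 4.4e-12 (adjusted p = 0.356 with an estimated correlation). Glycolysis had 10 falls and 1 rise among 19 genes (11 and 1 adjusted over the list alone). Lactate dehydrogenase Ldha was at -0.82 ± 0.09 and pyruvate kinase Pkm at -0.69 ± 0.09 (camera adjusted p = 2.3e-05; adjusted p = 0.281 with an estimated correlation). The pentose phosphate pathway had 5 falls among 7 genes (5 adjusted over the list alone). Taldo1 had the smallest p in it, at -0.69 ± 0.07 (camera adjusted p = 0.0004; adjusted p = 0.253 with an estimated correlation). One-carbon and nucleotide synthesis had 17 falls among 24 genes (20 adjusted over the list alone). The CTP synthase Ctps was at -0.62 ± 0.08 (camera adjusted p = 1.5e-10; adjusted p = 0.281 with an estimated correlation). Reactive oxygen defence had 8 falls and 2 rises among 21 genes (10 and 2 adjusted over the list alone). Thioredoxin reductase Txnrd1 was at -0.41 ± 0.07 and glutathione reductase Gsr at 0.40 ± 0.07 (camera adjusted p = 0.0224; adjusted p = 0.253 with an estimated correlation). Reactive oxygen defence did not pass without knockout replicate 2 (camera adjusted p = 0.0509) or wild-type replicate 2 (0.0862), or with the replicate number as a block (0.086). S phase genes had 22 falls and 1 rise among 42 (23 and 1 adjusted over the list alone). The histone chaperone Nasp was at -0.73 ± 0.08 and the helicase subunit Mcm5 at -0.52 ± 0.08 (camera adjusted p = 1.1e-09; adjusted p = 0.388 with an estimated correlation). Mcm5 did not pass with the same weight for each class (limma adjusted p = 0.0532).

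The lists that were higher in knockout included structural parts of the ribosome and genes of the αβ path. Of 80 cytosolic ribosomal protein genes, 25 rose and 1 fell (26 and 1 adjusted over the list alone). Rps24 was at 0.61 ± 0.16 and Rpl27a at 0.41 ± 0.11, but without wild-type replicate 1 neither passed (edgeR adjusted p = 0.0677 and 0.0926). Rps27l, an inducible paralogue, fell by 0.52 ± 0.10. Cytosolic ribosomal proteins had a camera adjusted p = 4.9e-12 (adjusted p = 0.467 with an estimated correlation). Interferon response genes had 13 rises and 1 fall among 28 (14 and 1 adjusted over the list alone). Isg15 was at 0.78 ± 0.09 and Ifit1 at 1.09 ± 0.15 (camera adjusted p = 1.8e-06; adjusted p = 0.433 with an estimated correlation). The αβ lineage and double-positive transition list had 11 rises and 1 fall among 22 genes (11 and 2 adjusted over the list alone). Beside Rorc, which also stands on the γδ lineage list, it held the transcription factors Ets2 (1.41 ± 0.09) and Lef1 (1.33 ± 0.09), with camera adjusted p = 7.5e-05 (adjusted p = 0.253 with an estimated correlation). Notch pathway genes had 5 rises among 16 (5 adjusted over the list alone), with Notch3 at 0.47 ± 0.08 beside Dtx1 (camera adjusted p = 0.00787; adjusted p = 0.253 with an estimated correlation). T cell commitment regulators had 8 rises and 3 falls among 24 (8 and 4 adjusted over the list alone). Ikzf3 was at 0.98 ± 0.09 and Gfi1 at 0.55 ± 0.08 (camera adjusted p = 0.0212; adjusted p = 0.253 with an estimated correlation). Cytokine receptors and homing genes had 11 rises and 3 falls among 23 (11 and 4 adjusted over the list alone). The CD6 receptor gene Cd6 was at 0.84 ± 0.09 and the integrin gene Itga4 at -0.92 ± 0.07 (camera adjusted p = 0.0143; adjusted p = 0.433 with an estimated correlation). Cytokine receptors did not pass without wild-type replicate 1 (camera adjusted p = 0.133).

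Several of these results changed with the same weight for each class, which also used limma in place of edgeR and left out the double-positive-like and macrophage-like classes and clusters 1, 3, 11 and 18. With the same weight for each class the median log2 fold change turned to -0.01 for Notch pathway genes, -0.04 for commitment regulators and -0.11 for cytokine receptors. That of the αβ list went from 0.23 to 0.00. Notch3, Ikzf3, Gfi1, Ifit1 and Cd6 did not pass under that weighting (limma adjusted p = 0.305, 0.0544, 0.0762, 0.232 and 0.942), nor did Notch3 in thinned cells (edgeR adjusted p = 0.29). In all, camera called 16 of 27 lists with its preset correlation, 10 lower and 6 higher. It called 0 with an estimated correlation, where the smallest adjusted p was 0.253. fry, which tests a list alone, called 15. Cytosolic ribosomal proteins (0.132), interferon response (0.0941) and cytokine receptors (0.0594) did not pass with it, while mTORC1 and mTORC2 components (0.0228) and the hypoxia response (0.0263) did.

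The other 11 lists did not pass. The γδ lineage list had 3 rises, among them Rorc, which also stands on the αβ list, and 5 falls among 18 genes (4 and 5 adjusted over the list alone; median log2 fold change -0.31, camera adjusted p = 0.318). It passed as lower without wild-type replicate 1 (camera adjusted p = 0.0265), and its direction turned without wild-type replicate 2 (0.962) and with fry. mTORC1 and mTORC2 components had 1 rise, that of the inhibitor Deptor (0.84 ± 0.12), and 5 falls among 29 (1 and 5 adjusted over the list alone; camera adjusted p = 0.0665). Eif4ebp1 (-0.66 ± 0.09) and Sesn3 (-0.66 ± 0.08) were among the falls, and Eif4ebp1 did not pass in thinned cells (edgeR adjusted p = 0.0794) or with the same weight for each class (limma adjusted p = 0.157). Without wild-type replicate 2 the mTORC1 and mTORC2 list passed as lower (camera adjusted p = 0.0474), as it did with fry (adjusted p = 0.0228). FOXO targets had 7 rises and 3 falls among 16 (7 and 4 adjusted over the list alone; camera adjusted p = 0.276), and passed as higher with the replicate number as a block (camera adjusted p = 0.0329). Foxo1 itself rose by 0.94 ± 0.10, but did not pass with the same weight for each class (limma adjusted p = 0.13). The FOXO median turned from 0.18 to -0.05 under that weighting and to -0.18 in thinned cells. G2 and M phase genes had 11 rises, among them Cenpf (0.73 ± 0.08), and 5 falls among 52 (11 and 5 adjusted over the list alone; camera adjusted p = 0.305). Their median was 0.02, and -0.04 with library sizes alone. The G2 and M list passed as higher without knockout replicate 2 (camera adjusted p = 0.0463) or wild-type replicate 1 (0.00952), and its direction turned without wild-type replicate 2 (0.83).

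D-type cyclins, cyclin-dependent kinases and their inhibitors had 7 rises, with Ccnd3 at 0.80 ± 0.08, and 3 falls among 21 (7 and 3 adjusted over the list alone). Their median was -0.01, their mean 0.28 and the test's direction upward (camera adjusted p = 0.318). The apoptosis and p53 list had 4 rises, among them Bcl2l1 (0.85 ± 0.10), and 3 falls, among them Bax (-0.61 ± 0.07), among 18 (4 and 5 adjusted over the list alone; camera adjusted p = 0.692). Receptor signal strength genes had 3 rises and 1 fall among 19 (3 and 1 adjusted over the list alone; camera adjusted p = 0.318). Their median was 0.16, and -0.22 with the same weight for each class. The hypoxia response had 2 rises and 4 falls among 17 genes (2 and 5 adjusted over the list alone; camera adjusted p = 0.318), and passed as lower with fry (adjusted p = 0.0263). Autophagy and lysosome genes had 1 rise and 5 falls among 36 (1 and 2 adjusted over the list alone; camera adjusted p = 0.321). Fatty acid oxidation had 0 rises and 1 fall among 16 (0 and 1 adjusted over the list alone; camera adjusted p = 0.318), and its direction turned without knockout replicate 3 (camera adjusted p = 0.992). Mitochondrially encoded genes had 0 rises and 3 falls among 11 (0 and 3 adjusted over the list alone; camera adjusted p = 0.114), and passed as lower without wild-type replicate 2 (camera adjusted p = 0.0203).

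To separate changes within a class of cells from changes in the mixture of classes, cells were classed by fixed marker genes. 3 classes held enough cells in every sample: a DN3-like, an S-phase-like and a G2-or-M-like class. The S-phase-like and G2-or-M-like classes are phases of the cell cycle and can hold several stages. A different mixture of stages or of cell-cycle phases within them was not separated from a change within a stage or phase. Markers of the cell cycle named these classes, so counts of cell-cycle lists within them also depend on where the clusters were cut. Knockout and wild-type cells of a class lay mostly in different clusters. DN3-like knockout cells lay mostly in clusters 4 (800, 805 and 735 cells) and 5 (975, 737 and 890), and DN3-like wild-type cells in cluster 7 (1444 and 1454). S-phase-like cells lay mostly in cluster 8 in knockout (428, 317 and 565) and cluster 9 in wild type (446 and 563). G2-or-M-like cells lay mostly in cluster 12 in knockout (575, 454 and 665) and cluster 17 in wild type (372 and 330). Cells of the cycling classes carried fewer UMIs in knockout. The median per sample was 9791.5 ± 413 (SD, n = 3) against 13813 ± 1937 (SD, n = 2) in the S-phase-like class. It was 9109.5 ± 202 against 15218 ± 1918 in the G2-or-M-like class, and 3657 ± 256 against 3507 ± 620 in the DN3-like class. Within each sample the S-phase-like median was 2.68 ± 0.0812 times the DN3-like one in knockout and 3.95 ± 0.147 times in wild type. The 3 knockout samples lay below both wild-type samples (exact permutation test, two-sided, p = 0.1, the smallest that 10 splits allow).

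**Figure D2:**
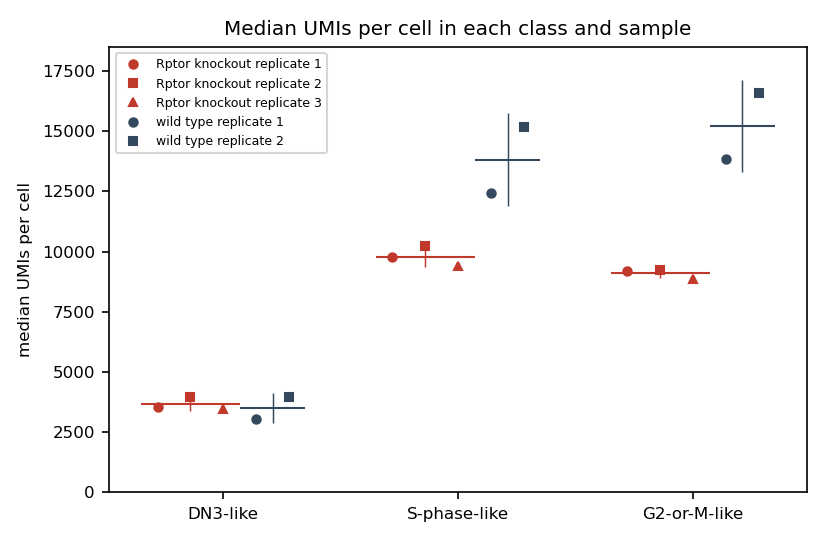
Median UMIs per cell in each class for each sample, with the mean and SD of 3 knockout and 2 wild-type samples. In the S-phase-like and G2-or-M-like classes every knockout sample lies below both wild-type samples, while the DN3-like medians overlap.

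In the DN3-like class, Nnat was at 40.3 ± 2.17 CPM (SD, n = 3) in knockout, with 809 UMIs, and had 0 UMIs in wild type. It was at least 168-fold higher against a floor of 3 counts over the wild-type group, a bound for counting error only. The interferon-inducible Ifi204 rose from 1.43 ± 0.009 to 17.2 ± 5.49 CPM, Tcte2 from 3.98 ± 0.426 to 26.2 ± 2.14 CPM and the growth factor gene Pdgfa from 7.81 ± 1.37 to 44.6 ± 13.5 CPM. Ccr9 fell from 160 ± 15.7 to 35.4 ± 9.67 CPM and Tdrd5 from 22.4 ± 2.25 to 5.62 ± 1.5 CPM. Gm37552 fell from 33.2 ± 6.49 to 9.14 ± 2.03 CPM and Cdk5rap1 from 32.7 ± 10.3 to 12.1 ± 3.17 CPM. Without wild-type replicate 1 Pdgfa and Ccr9 did not pass (edgeR adjusted p = 0.302 and 0.0866), nor without wild-type replicate 2 (0.222 and 0.0527). edgeR called 412 of 10846 genes, 230 higher and 182 lower, against 151 higher and 333 lower with library sizes alone (31.2% against 55.8% higher). DESeq2 called 256, the test without a filter on low counts called 798, and edgeR called 234 without knockout replicate 1.

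camera called 6 lists in the DN3-like class, each with adjusted p = 0.617 with an estimated correlation. Interferon response genes had 7 rises and 0 falls among 26 (9 and 0 adjusted over the list alone; camera adjusted p = 2.8e-06). Notch pathway genes had 2 rises among 16 (3 adjusted over the list alone; camera adjusted p = 0.00252), with a median of 0.09 that was 0.00 with library sizes alone. Sterol and fatty acid synthesis had 1 fall among 29 (10 adjusted over the list alone; camera adjusted p = 0.000424). Glycolysis had 3 falls among 17 (4 adjusted over the list alone; camera adjusted p = 0.0255) and S phase genes 2 among 42 (5 adjusted over the list alone; camera adjusted p = 0.0215). The cytosolic ribosomal protein list was called higher as a group (camera adjusted p = 3.8e-16) although edgeR called 0 of its 79 genes, and 0 adjusted over the list alone. Of these, 15 were higher at an unadjusted p under 0.05 and DESeq2 called 3. Of the 40 ribosome biogenesis genes edgeR called 0, and 0 adjusted over the list alone (median log2 fold change -0.07; camera adjusted p = 0.0985). At an unadjusted p under 0.05, 3 of them were lower, and DESeq2 called 0.

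In the S-phase-like class, Nnat was at 190 ± 17.2 CPM in knockout and 0.059 ± 0.083 CPM in wild type. Tox2, a nuclear factor of the TOX family, rose from 2.24 ± 1.0 to 17.2 ± 4.95 CPM, Arsi from 2.73 ± 1.69 to 18.5 ± 4.45 CPM and Cd2 from 19.7 ± 4.0 to 117 ± 20.1 CPM. The branched-chain aminotransferase gene Bcat1 fell from 23.1 ± 4.5 to 5.71 ± 2.31 CPM and 1110008P14Rik from 17.8 ± 2.31 to 4.85 ± 0.663 CPM. Hsph1 fell from 68.8 ± 0.421 to 21.7 ± 5.53 CPM and Dqx1 from 52.0 ± 16.6 to 16.3 ± 6.31 CPM. Dqx1 did not pass without knockout replicate 1 (edgeR adjusted p = 0.108) or with classes of a wild-type clustering (0.0647). Of 40 ribosome biogenesis genes 39 fell (39 adjusted over the list alone; camera adjusted p = 6.8e-27; adjusted p = 0.162 with an estimated correlation). Of 78 cytosolic ribosomal protein genes 58 rose and 1 fell (64 and 1 adjusted over the list alone; camera adjusted p = 3.7e-16; adjusted p = 0.387 with an estimated correlation). G2 and M phase genes had 29 rises and 2 falls among 52 (33 and 3 adjusted over the list alone; camera adjusted p = 8.9e-11; adjusted p = 0.162 with an estimated correlation). S phase genes had 10 rises and 9 falls among 42 (10 and 11 adjusted over the list alone; camera adjusted p = 0.625). The G2 or M phase marker Top2a was seen in 87.9%, 90.3% and 86.3% of thinned knockout and 71.1% and 74.5% of wild-type cells of this class. A different mixture of phases therefore stays open for the cell-cycle lists here. edgeR called 3652 of 10147 genes, 1776 higher and 1876 lower, against 1243 higher and 2154 lower with library sizes alone (36.6% against 48.6% higher). DESeq2 called 2209.

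In the G2-or-M-like class, Nnat was at 288 ± 10.3 CPM in knockout and 0.364 ± 0.106 CPM in wild type. Tox2 rose from 2.55 ± 1.77 to 19.9 ± 7.3 CPM, Arsi from 5.67 ± 0.16 to 38.6 ± 1.96 CPM and Cd2 from 17.5 ± 6.1 to 115 ± 22.2 CPM. Hsph1 fell from 53.4 ± 1.35 to 12.2 ± 1.98 CPM and Tmem238 from 21.5 ± 3.05 to 5.02 ± 1.57 CPM. The mitochondrial nuclease gene Endog fell from 44.2 ± 5.91 to 11.1 ± 2.11 CPM and Dqx1 from 50.7 ± 1.44 to 14 ± 2.42 CPM. Ribosome biogenesis fell in 40 of 40 genes (40 adjusted over the list alone; camera adjusted p = 4.4e-25; adjusted p = 0.251 with an estimated correlation). MYC targets fell in 22 of 25 (22 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.8e-17; adjusted p = 0.245 with an estimated correlation). Glycolysis fell in 12 of 18 (13 adjusted over the list alone; camera adjusted p = 6.0e-07; adjusted p = 0.245 with an estimated correlation). G2 and M phase genes had 35 rises and 0 falls among 52 (37 and 0 adjusted over the list alone; camera adjusted p = 8.9e-14; adjusted p = 0.245 with an estimated correlation). The S phase marker Pcna was seen in 43.5%, 40.9% and 31.1% of thinned knockout and 61.0% and 53.5% of wild-type cells of this class. Since G2 or M phase markers also named the class, a different mixture of phases stays open for that list. edgeR called 3813 of 10412 genes, 1764 higher and 2049 lower.

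Whether the effect of the knockout differed between the DN3-like and the S-phase-like class was tested as an interaction with the sample as a block. The S-phase-like class may hold another mixture of stages or cell-cycle phases in knockout, which the test does not take out. Ccng2, an atypical cyclin and FOXO target (chromosome 5, 93267257 to 93276231), had a log2 fold change of -0.64 in the DN3-like and 1.81 in the S-phase-like class. The difference was 2.40 ± 0.14 (SE; n = 3 knockout and 2 wild-type samples). It was 1.96 ± 0.14 for Zbtb20, a zinc finger repressor (0.33 and 2.32), 1.83 ± 0.25 for the kinase gene Txk (0.20 and 2.0) and 1.86 ± 0.31 for Gm37552 (-1.86 and 0.04). It was -2.03 ± 0.30 for the interferon-inducible Ifitm3 (2.0 and -0.06) and -1.74 ± 0.29 for Ly6c1 (0.63 and -1.18). For Fam212a it was -1.65 ± 0.24 (0.80 and -0.86) and for Ldlr, the LDL receptor gene, -1.63 ± 0.20 (0.13 and -1.47). Over all cells, where Ccng2 rose, it did not pass in thinned cells (edgeR adjusted p = 0.301) or with the same weight for each class (limma adjusted p = 0.676). The difference was negative past the test for 38 of 40 ribosome biogenesis genes (38 adjusted over the list alone; DESeq2 32). It was negative for 69 of 85 oxidative phosphorylation genes and positive for 3 (71 and 3 adjusted over the list alone; DESeq2 53 and 1). It was negative for 20 of 29 genes of sterol and fatty acid synthesis (22 adjusted over the list alone; DESeq2 11). Of 52 G2 and M phase genes it was positive for 20 and negative for 1 (23 and 2 adjusted over the list alone; DESeq2 8 and 0). edgeR called 3134 of 11061 genes, 1262 with a positive and 1872 with a negative difference, against 1448 and 1581 with library sizes alone. DESeq2 called 1279.

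**Figure D3:**
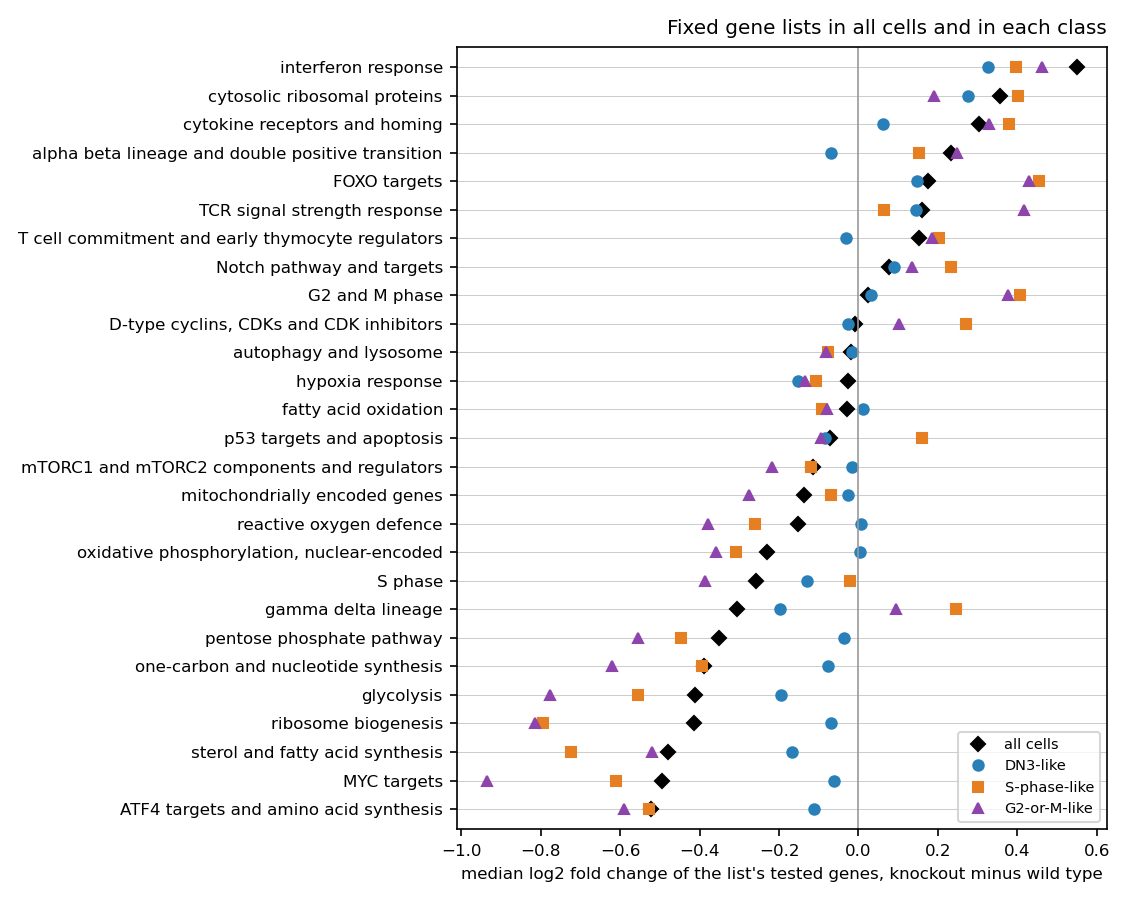
Median log2 fold change (knockout minus wild type) of the tested genes of each pathway list, in the sums over all cells and over each class of 3 knockout and 2 wild-type samples. Ribosome biogenesis lies at -0.07 in the DN3-like class and at -0.79 and -0.82 in the cycling classes. The all-cell medians drawn for the Notch, FOXO, signal strength, commitment and cytokine receptor lists lie above 0. With the same weight for each class, which is not drawn, these medians lie below 0.

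The shares of kept cells per class asked whether the stages were filled differently. The DN3-like class, named where markers such as Il2ra and Ptcra were at least 1.5-fold higher than in the other cells, held 34.2% ± 3.64 (SD, n = 3) of knockout and 38.2% ± 1.82 (SD, n = 2) of wild-type cells. The S-phase-like class held 8.60% ± 1.27 and 11.2% ± 1.65, and the G2-or-M-like class 11.8% ± 0.733 and 10.2% ± 0.949. A class with markers of the immature single-positive and double-positive stages, led by Cd8b1, Rorc and Cd8a, held 6.30%, 8.87% and 5.36% of knockout cells and 0.112% and 0.087% of wild-type cells. This class is called double-positive-like for short, and the name covers both stages. Against a clustering of wild-type cells alone it held 4.80%, 6.80% and 4.86% of knockout cells and 2.40% and 3.28% of wild-type cells. No cluster took that name at resolution 0.5, with no doublets removed, with all deposited barcodes, or with cell-cycle genes or called genes left out of the clustering. In the last 4 of these settings a cluster with nearly the same top genes, among them Cd8b1 and Txk, was named γδ T cell, with 6 of 7 markers higher. With all deposited barcodes it held 269, 316 and 237 knockout and 20 and 24 wild-type cells. The markers therefore do not settle whether these cells are double-positive-like or γδ-like. A macrophage-like class held 24 cells, and 38.5% ± 3.27 of knockout and 40.3% ± 1.10 of wild-type cells had no class. Many cells without a class lay in different clusters in the groups. Cluster 1 held 873, 606 and 1203 knockout and 11 and 19 wild-type cells, and cluster 11 held 345, 282 and 493 and 0 and 4. Cluster 18 held 12, 2 and 4 knockout and 734 and 809 wild-type cells. Clusters 0, 6, 10, 14 and 16 held at least 30 cells in every sample. The shares are given as values only, since genes that differ between the groups also shaped the clusters and the sort excluded CD4- and CD8-bearing cells. The exact permutation test (two-sided, 10 splits) gave its smallest possible p, 0.1, for the G2-or-M-like and the double-positive-like class. It gave 0.2 for the S-phase-like and 0.3 for the DN3-like class. The sign of the difference turned with the clustering resolution for the DN3-like and G2-or-M-like classes and with the cell filter for the cycling classes. The names moved between clusters in these settings, so the turns do not give the sign of a change in stage.

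A count of cells with a UMI after thinning every cell to 2000 UMIs needed no clusters. Cd8b1 was seen in 20.2% ± 1.92 (SD, n = 3) of knockout and 9.35% ± 1.59 (SD, n = 2) of wild-type cells, and Rorc in 6.36% ± 0.328 and 1.51% ± 0.232. Cd24a, a marker of immature thymocytes, was seen in 48.7% ± 1.72 and 59.5% ± 0.100. Id3 was seen in 9.18% ± 1.77 and 15.6% ± 0.894 and Tfrc in 3.8% ± 0.272 and 6.07% ± 0.121. Within the G2-or-M-like class Cd8b1 was seen in 39.0%, 47.0% and 36.0% of knockout and 15.8% and 20.4% of wild-type cells. In the DN3-like class it was seen in 3.17%, 3.92% and 3.20% and in 2.49% and 3.18%. For these 5 genes all knockout samples lay on 1 side of both wild-type samples over all cells (exact permutation test, two-sided, p = 0.1, the smallest possible, and 0.164 adjusted over 18 genes). Other genes of the 18 reached this p as well, so these 5 are examples and not a full count. In the 24 macrophage-like cells Il2ra had a UMI in 14 cells (58.3%), Cd24a in 13 (54.2%), Cd8b1 in 4 (16.7%), Rorc in 2 (8.33%), Tfrc in 1 and Id3 in 0. These cells had a median of 4105 UMIs against 5591.5 over all cells. The Rorc value lay above the shares of both groups, the Il2ra value too, that of Cd8b1 above the wild-type share and that of Cd24a between the groups. Some classes of thymocytes lay lower and others higher. Cd8b1 was lower in the DN3-like class, as above, and seen in 77.0%, 83.0% and 82.8% of double-positive-like knockout cells, where Il2ra was seen in 9.09%, 9.04% and 8.61%. The macrophage-like cells therefore do not give the level of free RNA, which stays unknown here. Within the knockout samples Rorc was seen in 0.897%, 1.24% and 1.3% of DN3-like and 15%, 13.3% and 10.3% of G2-or-M-like cells. In the double-positive-like class, which Rorc helps to name, it was seen in 25.5%, 21.5% and 21.2%. Cd4 was seen there in 5.76%, 3.19% and 4.97%, against 0.693%, 0.484% and 0.615% of all knockout cells. Cd8a was seen there in 10.3%, 12.0% and 11.9%, against 2.42%, 2.74% and 2.83% of all knockout cells. These shares do not settle whether the cells had reached the immature single-positive or the double-positive stage. Il2ra was seen in 44.6% ± 3.51 and 41.9% ± 2.48 of all cells, and the sign of the gap turned without thinning. In the DN3-like class, which Il2ra helps to name, it was seen in 85.6%, 83.6% and 85.0% of knockout and 68.7% and 63.4% of wild-type cells. Ptcra was seen there in 79.3%, 71.3% and 78.0% of knockout and 73.9% and 70.2% of wild-type cells, ranges that overlap. In the S-phase-like class Ptcra was seen in 25.7%, 25.8% and 26.4% of knockout and 17.4% and 14.4% of wild-type cells.

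**Figure D4:**
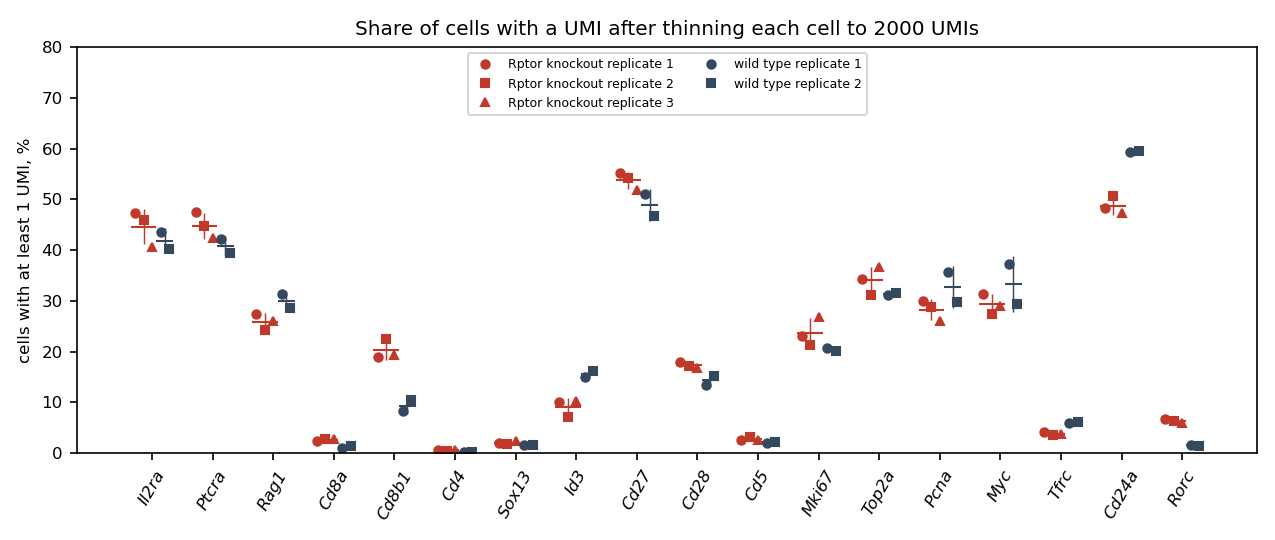
Percent of cells with a UMI of each gene after thinning to 2000 UMIs per cell, for each of 3 knockout and 2 wild-type samples, with the mean and SD of each group. Cd8b1 lies between 18.9% and 22.4% in knockout and at 8.22% and 10.5% in wild type.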

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

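The tests of the window on chromosome 2, of the depth of the knockout libraries, of the UMIs in the class sums and of calls under the wild-type clustering were chosen only after the result was seen. The effect of the knockout differed between the DN3-like and the S-phase-like class in the interaction test for 3134 genes. Among the named genes the difference in log2 fold change was 2.40 for Ccng2, 1.96 for Zbtb20, 1.86 for Gm37552, 1.83 for Txk, -2.03 for Ifitm3, -1.74 for Ly6c1, -1.65 for Fam212a and -1.63 for Ldlr.

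The DN3-like class had 412 calls and the S-phase-like class 3652. The DN3-like sums held more UMIs than the S-phase-like sums in all knockout samples and in the wild-type sample with fewer UMIs. They held fewer only in the other wild-type sample. Sums thinned to the same total lost more UMIs in most DN3-like sums, so the thinning could not test fewer DN3-like UMIs as a cause. With these thinned sums the S-phase-like class had 3069 calls and the DN3-like class 295, a ratio of 10.4. With classes of the wild-type clustering the calls were 3286 and 436, a ratio of 7.54, which argues against the joint clusters as the cause. A larger spread between DN3-like samples as the only cause was argued against by the sizes of the changes. Over 6836 genes the median absolute log2 fold change was 0.12 in the DN3-like and 0.26 in the S-phase-like class, a ratio of 0.467. The spread itself was not measured there, so a part played by it stays open. Neither a stronger dependence of cycling thymocytes on RAPTOR nor a different mixture of stages or phases within the S-phase-like class was tested.

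Nnat stood at 184.9 CPM in knockout and 0.149 CPM in wild type, and 11 genes changed more than 2-fold between 150 and 160 Mb of chromosome 2, 9.82% of the 112 tested there against 2.65% of all genes with a position. For a few cells of another type the value named beforehand did not decide, since the 1% of knockout cells with the most held 13.3% of the Nnat UMIs, between the bounds of 10% and 50%. The explanation was argued against by the shares of thinned knockout cells with a Nnat UMI. These were 5.96%, 6.16% and 6.21% in the DN3-like and 34.2%, 34.1% and 34.1% in the G2-or-M-like class of the same samples, while RNA set free by a few cells would reach both classes alike. The crowding on chromosome 2 exceeded that after shuffling positions (permutation test, p = 0.0201 over 10000 shuffles and 276 windows). A chromosome segment that differs between the mice of the groups may account for the window, and it stays open. Imprinted genes as a group stayed undecided, since 18.5% of 27 not seen before rose, Igf2 among them, against 12.9% of other genes (Fisher's exact test, two-sided, p = 0.383). Nnat lies inside Blcap (157556362 to 157571274) on the other strand, and how the counting treated strands is not given in the sources used here.

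The S-phase-like class had 2.68 times the UMIs per cell of the DN3-like class in knockout and 3.95 times in wild type, with a gap of 1.11 between the nearest samples of the groups. Doublets that the score ranks high were argued against, since the gap was 1.20 with the 10% of cells with the highest doublet scores removed from every sample. Scrublet marked only 3 and 2 wild-type cells, so doublets that its score misses stay open. Different clusters in the groups were argued against as well. Cells with 2 or more G2 or M phase marker UMIs had 1.82 times on average the UMIs of cells with none in knockout and 3.13 times in wild type, a gap of 1.11. A lower depth of the knockout libraries was argued against by the DN3-like cells, whose median UMIs in knockout were 1.04 times those in wild type. A smaller RNA content of cycling cells without RAPTOR was not tested, since that needs RNA added to each cell in a known amount.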

How the results depend on the processing

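The equal removal of doublets, the droplets with haemoglobin left out, the wild-type clustering and the thinned sums in the class tests, the lists in class sums, the cycling classes as 1 class and the clustering without called genes were chosen only after the result was seen. Where values changed, the cause was not tested. The same weight for each class left out classes and clusters with fewer than 30 cells in a sample and used limma.

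The number of genes called over all cells went from 3444 to 1397 with cells thinned to 2000 UMIs and to 1094 with the same weight for each class. In the DN3-like class 412 became 256 with DESeq2 and 798 without a filter on low counts. With DESeq2 the 3652 calls of the S-phase-like class became 2209 and the 3134 of the interaction 1279. The 16 lists called became 0 with an estimated correlation and 6 in DN3-like sums.

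With each replicate left out in turn the calls ranged from 1956 to 2921 over all cells, 234 to 444 in the DN3-like, 2519 to 3136 in the S-phase-like and 2590 to 3459 in the G2-or-M-like class. They ranged from 2207 to 2816 for the interaction, and the lists from 16 to 17. The adjusted p ranged from 0.1121 to 0.9922 for fatty acid oxidation, 0.009517 to 0.83 for G2 and M phase and 0.02654 to 0.9624 for the γδ lineage list. The log2 fold change ranged from -0.1211 to 0.0026 for Rag1 and from -0.3467 to 0.0125 for Myc. A lone wild-type sample was taken to vary like the knockout samples.

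With the replicate number as a block edgeR called 4447 genes over all cells, 474 in the DN3-like, 3622 in the S-phase-like and 3687 in the G2-or-M-like class. Since only knockout has a replicate 3, that sample adds nothing to the comparison under the block. The block gave 2917 for the interaction and 16 lists. Fatty acid oxidation (adjusted p = 0.8834) and the p53 list (0.8255) turned direction with it and FOXO targets passed (adjusted p = 0.03291), and fry turned the γδ lineage list (0.9389). The residuals of samples with the same number correlated at 0.338 for number 1 and 0.109 for number 2, and with 2 shared numbers this does not pair the samples.

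The difference in share, knockout minus wild type in percentage points, was 27.8189 for the DN3-like and -0.5039 for the G2-or-M-like class at resolution 0.5. There no cluster was named S-phase-like, and 72.9% and 73.2% of wild-type cells had no class. With all deposited barcodes the difference was 9.0708 for the S-phase-like and -9.2082 for the G2-or-M-like class. These held 3 and 6, and 873 and 952, wild-type cells. The stricter cell filter gave 7.6191 and -7.0132, with 6 and 13, and 810 and 908, wild-type cells. It gave 0.6059 for the cycling classes as 1 class. Names thus moved between clusters in these settings. The double-positive-like class has no value at resolution 0.5, with no doublets removed, with all deposited barcodes, or with cell-cycle or called genes left out, since no cluster took the name. The difference was -0.412 for the G2-or-M-like class with cell-cycle genes left out of the clustering, where no cluster was named S-phase-like either. Against the wild-type clustering it was -0.3767 for the macrophage-like class, there a cluster of 333 cells led mostly by interferon genes in place of 24 cells, and 1.0759 for the cycling classes as 1 class, which were at 0.1512 with no doublets removed. Without thinning, the share of cells with a UMI differed by -2.7523 for Il2ra, -1.9223 for Mki67 and -0.3855 for Top2a. With the same weight for each class the log2 fold change was 0.0702 for Mtor and -0.4779 for Cd8a.

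Of the values of 82 genes named over all cells under these alternatives, 1420 kept their direction and side of the threshold, 35 lost the call, 14 gained it and 4 turned direction. For 24 results of genes in the classes 258 kept both and 6 lost the call, and for 8 genes of the interaction 88 kept both. For the 27 lists the numbers were 260, 23, 8 and 6. Every alternative planned was run. With 3 and 2 samples an exact permutation test cannot give a p under 0.1, and genes removed by the filter on low counts were tested only in the alternative without it.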

Other observations

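The tests reported for Igf2 and Blcap were chosen only after the result was seen. Imprinted genes beside Nnat were among those that moved. Igf2, a fetal growth factor gene, rose from 0.467 ± 0.16 (SD, n = 2) to 6.13 ± 3.21 CPM (SD, n = 3), with an edgeR adjusted p of 0.0309. It did not pass without knockout replicate 1 (0.0884), wild-type replicate 1 (0.193) or wild-type replicate 2 (0.192). Cdkn1c, a growth-restraining inhibitor of cyclin-dependent kinases in the same imprinted region as H19, rose from 1.03 ± 0.077 to 2.96 ± 0.117 CPM, but did not pass with the same weight for each class (limma adjusted p = 0.247). Blcap, which overlaps Nnat on the other strand, rose from 12.4 ± 1.43 to 33.3 ± 0.762 CPM. Of 27 imprinted genes not seen before the count, 5 rose, Igf2 among them, and 3 fell.

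Markers of thymocyte stages and of other cell types moved as follows over all cells, although the sort against lineage markers, CD4, CD8 and both T cell receptors would remove mature T cells, B cells, erythroid cells and other lineages. Cpa3, a mast cell protease gene that early T cell progenitors also express, fell from 13 ± 3.25 to 2.81 ± 1.13 CPM, and the chemokine gene Ccl5 of natural killer and effector T cells rose from 0.658 ± 0.284 to 3.38 ± 0.572 CPM. Ms4a4b and Ms4a6b, membrane genes of mature T cells, fell by 1.03 ± 0.13 and 0.74 ± 0.08 on the log2 scale, and Cox6a2 of plasmacytoid dendritic cells fell from 2.56 ± 1.07 to 0.432 ± 0.271 CPM. Cox6a2 did not pass in thinned cells (edgeR adjusted p = 0.142). Kit, the stem cell factor receptor of early progenitors, fell by 0.59 ± 0.12. Of the measured markers, 1 rose and 4 fell among 8 of early thymocytes (1 and 5 adjusted over the list alone). The rises and falls were 5 and 2 of 11 for the DN3 stage (6 and 3) and 4 and 4 of 12 for β-selected cells (4 and 4). They were 5 and 0 of 8 for the single-positive and double-positive stages (5 and 0), 2 and 1 of 7 for γδ T cells (2 and 1) and 0 and 3 of 8 for mature αβ T cells (0 and 3). The numbers were 0 and 9 of 12 for S phase (0 and 9), 3 and 1 of 14 for G2 or M phase (4 and 2), 1 and 1 of 6 for natural killer cells (1 and 3), 2 and 1 of 5 for other innate lymphoid cells (2 and 1), 1 and 0 of 9 for macrophages and dendritic cells (0 and 0), and 1 and 2 of 6 for plasmacytoid dendritic cells (1 and 2). There was 1 fall of 1 for mast cells (1) and 1 of 2 for fibroblasts and endothelium (1). edgeR called 0 of 3 genes for B cells, 0 of 7 for erythroid cells, 0 of 2 for thymic epithelium and 0 of 5 sex-linked genes, and 0 adjusted over each list alone. At an unadjusted p under 0.05 the count was 1 for B cells and 0 for the others, and DESeq2 called 0 in each.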
